A study of Plasmodium falciparum 3D7 with 10 samples.

How the data were processed

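Plasmodium falciparum 3D7 was cultured in red blood cells with or without the bisthiazolium T4, and total RNA was hybridised to a 1-colour biotin-labelled oligonucleotide array, per the labels. The series holds 10 arrays in 5 pairs of an untreated and a treated culture, at 30 min and 5 h with 125 nM T4 and at 24, 30 and 36 h with 40 nM T4, with 1 array per condition. Doses and times come from the sample titles, since the description of the study names only 125 nM. Neither source says whether cultures of one experiment were started together, nor which were mixed and which synchronised.

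The deposited values are intensities, 1 per feature and array, as whole numbers from 1 to 38788. The authors' summarisation, background correction and scaling are not given in the sources used here. The array medians were 114, 99, 103 and 104 in the 125 nM experiment (untreated and treated at 30 min, then at 5 h) and 51, 60, 26, 43, 41 and 82 in the 40 nM experiment (the same order at 24, 30 and 36 h), so the arrays had not been brought to a common median. The 5th percentile ran from 16 to 29 in the first experiment and from 4 to 7 in the second. The number of arrays limits the precision.

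Each array was scaled to a common median, values were floored at the 25th percentile of all scaled values (26.1), and log2 was taken. Log2 ratios at a single time compare 1 treated with 1 untreated array, carry no test, and understate the change of genes near the floor. A gene counted as changed at a time when it was at least 2-fold apart with the brighter array above the floor. Where the dimmer array lay at the floor, the fold is a lower bound and is given as at least that size.

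For the tests, genes above the floor on fewer than 2 arrays were left out, which left 4512 of 5159. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), with the incubation-time pair as a block and 1 T4 coefficient per experiment, leaving 3 residual degrees of freedom. The pairing comes from the times in the sample titles. Further fits gave 1 T4 coefficient over all times and the difference of the experiments. The adjusted p is limma's two-sided p after Benjamini-Hochberg adjustment, with a threshold of 0.05. The times stand as repeats, so these p-values measure the spread between times and not between cultures of one time. On simulated data for the 40 nM comparison with 4512 genes, 56, 96, 98 and 96% of genes changed by 1, 2, 3 and 4 on the log2 scale passed the threshold, and 17 unchanged genes passed too. For the 125 nM comparison these shares were 38, 92, 98 and 98%, with 8 unchanged genes passing. Each simulated change had the same size at every time of the experiment, and the noise was independent between genes. The shares therefore do not hold for changes that differ between times.

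Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 15 lists, with an estimated correlation and with fry as alternatives. At single times, list medians were ranked among 10000 random lists of equal size matched on mean expression in 20 bins. Of the lists, 6 were fixed before the data were examined (phospholipid synthesis, ring stage, haemoglobin digestion, DNA replication, merozoite and invasion, gametocyte), and 89 of their 96 members were kept. Left out were 4 members without a feature of their ID (CCT, CEPT, MAHRP1, EBA175), 2 without a row in the platform annotation and 1 with another current tag (HAP2). The current tag of EBA175 is carried by a feature of another ID, PF07_0128, so EBA175 was measured but not counted in its list. That feature had a log2 ratio of -5.55 at 36 h. Another 7 lists, with 68 members, were written by ID when the feature names were known and the values had not been looked at (glycolysis, chaperones and heat shock, histones and nucleosome assembly, proteasome, redox defence, ribosomal proteins and translation, export machinery and vacuole membrane), and 2 came from feature names (organelle genome transcripts, ribosomal RNA features). Of 15 lists planned by product text, which the reference does not hold, 6 were rebuilt by ID, and those for further lipid enzymes, transfer RNA ligases, the proton ATPase, var, rifin, stevor, exported families, protein kinases and AP2 factors were not run.

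The platform annotation pairs 4661 features with 1 gene, none with several, and leaves 498 unlisted. A current gene table of the 3D7 assembly was used for tags and for which genes neighbour each other. The series names no genome build, so no coordinates are given.

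The rule for named genes was set before the data were examined. Per experiment it takes the 12 genes up and the 12 down with the largest smallest log2 ratio among genes above the floor on every array and changed the same way at each time. Per time it takes the 5 highest and 5 lowest log2 ratios among genes above the floor on both arrays, and per fit up to 10 genes each way past the threshold. Members of the lists may be named with their list, genes of the var, rifin and stevor families are not named singly, and few IDs without a name are printed.

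The alternatives set out before the data were examined were no scaling, quantile normalization, floors at the 10th and 40th percentile, a 3-fold threshold, Spearman in place of Pearson correlation, no pair block, and leaving out each pair. Scaling to a common 90th percentile, cyclic loess, leaving out features that share one value per array, the other list tests for the difference of the experiments, and the 24 h pair left out under each scaling were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.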

Results

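Transcript levels were measured in Plasmodium falciparum 3D7, the reference clone of the human malaria parasite, grown in red blood cells with or without T4, a bisthiazolium compound. Bisthiazolium drugs are choline analogues that interfere with the synthesis of phosphatidylcholine, the main membrane phospholipid of the parasite. Total RNA was hybridised to a 1-colour biotin-labelled oligonucleotide array with 5159 features. In one experiment, cultures were sampled 30 min and 5 h after the addition of 125 nM T4, each beside an untreated culture (4 arrays). In the other, cultures were sampled 24, 30 and 36 h after the addition of 40 nM T4, again each beside an untreated culture (6 arrays). The doses are those of the sample titles, while the general description of the study names only 125 nM. That description speaks of mixed or synchronised cultures and does not say which were used at which time. Each of the 10 conditions was measured on 1 array, so a value at a single time has no replicate check, and the number of arrays limits the precision. The median intensity of the arrays ran from 26 to 114, and after scaling between 69.6% and 82.3% of the features lay above the intensity floor of 26.1.

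The comparison at each incubation time asked how the treated culture differed from its untreated partner. During the first hours with 125 nM T4 the arrays differed little, and the largest differences came at 30 and 36 h with 40 nM T4. At 36 h, REX1 (PFI1735c), a protein that the ring-stage parasite exports to membrane clefts in the red cell, was 31.3-fold lower in the treated culture. In the same culture MDV1 (PFL0795c), a protein of developing gametocytes, was 7.07-fold higher. These folds hold for scaling to a common median, which multiplied the untreated 36 h array by 1.59 and the treated one by 0.80. With no scaling such a fall would be smaller and such a rise larger. At 24 h, RAP1 (PF14_0102), a rhoptry protein used during invasion of the red cell, was among the 5 genes with the lowest log2 ratios, at -2.13. At 30 min, the highest log2 ratios, 2.95 and 2.39, were those of a pair of ribosomal RNA features, and the same features had log2 ratios of -0.51 and -0.86 at 5 h. The latter feature had 0 at 24 and 36 h and the highest log2 ratio, 3.63, at 30 h.

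Counted on arrays scaled to a common median, 35 genes were at least 2-fold higher and 91 at least 2-fold lower at 30 min. The counts were 17 higher and 16 lower at 5 h, 115 and 132 at 24 h, 312 and 582 at 30 h, and 582 and 957 at 36 h. The SD of the log2 ratios across genes followed the same order, at 0.42, 0.28, 0.46, 0.78 and 1.06. The rule for genes with log2 ratios of one sign at 24, 30 and 36 h picked 12 lower genes, of which 6 belong to the gene lists. These were RON2 and the merozoite surface proteins MSP2 and MSP4, which take part in invasion, the export components HSP101 and TRX2, and ethanolamine kinase (EK) of phospholipid synthesis. None of the 12 higher genes belongs to the gene lists, which were the only source of gene names here. The foremost of them, PF13_0144, had log2 ratios of 1.74, 2.67 and 2.02 at 24, 30 and 36 h, and PF13_0128 had 1.66, 1.64 and 1.93. Among the lower genes outside the lists, PFI0270w had log2 ratios of -1.66 and -1.93 at 24 and 30 h.

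How the calls divided between higher and lower depended on the scaling of the arrays. With no scaling, 10 genes were higher and 367 lower at 30 min, 193 and 56 at 24 h, 863 and 137 at 30 h, and 1606 and 295 at 36 h. With no scaling the median log2 ratio of all genes itself lay at -0.16 at 30 min and at 0.34 at 36 h. Quantile normalization gave 398 higher and 412 lower at 30 h and 785 and 657 at 36 h. Scaling to a common 90th percentile gave 9 and 205 at 30 min, 20 and 12 at 5 h, 184 and 81 at 24 h, 613 and 315 at 30 h, and 1205 and 454 at 36 h.

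**Figure D1:**
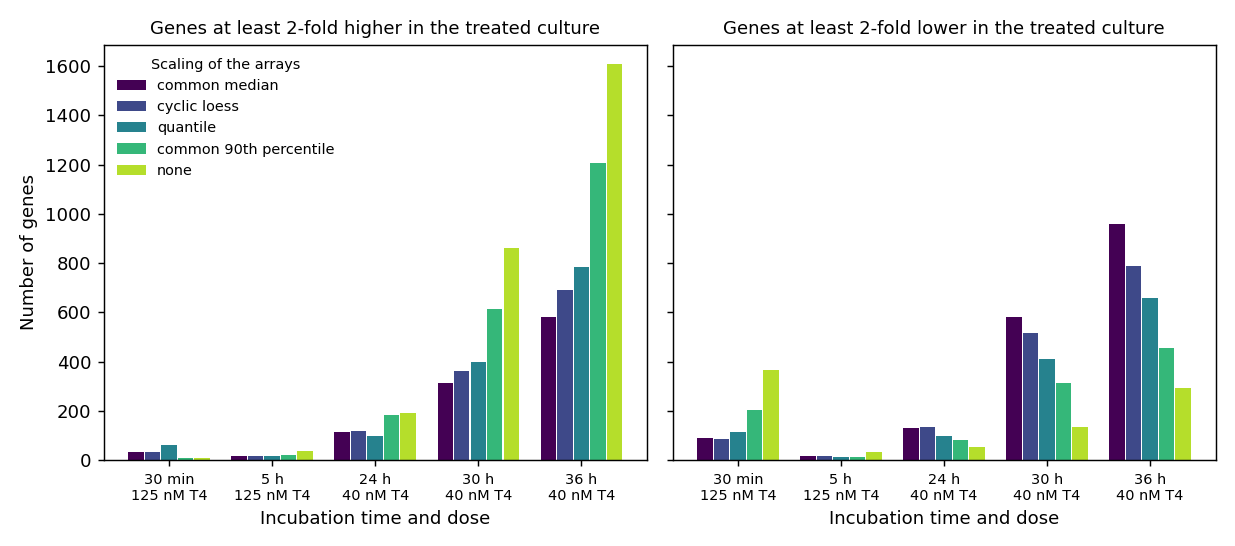
Number of genes at least 2-fold higher (left) or lower (right) in the T4-treated than in the untreated culture, by incubation time and dose on the horizontal axis, with 1 bar for each of 5 ways of scaling the arrays. With scaling to a common median, 582 genes were higher and 957 lower at 36 h, against 17 and 16 at 5 h, and with no scaling the split at 36 h was 1606 and 295.

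The gene lists at single times asked which groups of transcripts stood apart on the paired arrays, and each median was ranked among 10000 random lists of equal size matched on mean expression. The 29 transcripts for merozoite and invasion proteins had medians 1.62-, 2.31- and 3.42-fold lower in the treated culture at 24, 30 and 36 h, below every random list at each of these times. With the floor at the 40th percentile the 24 h median was -0.18 on the log2 scale, at the 48.2th percentile. Of them, 8, 20 and 25 were at least 2-fold lower at 24, 30 and 36 h. The 5 transcripts of the list for export machinery and the vacuole membrane had medians 2.52-fold lower at 30 h and 7.44-fold lower at 36 h. The 13 ring-stage transcripts had medians 2.99- and 3.00-fold lower at those times, with 7 members at least 2-fold lower at each. The 15 transcripts of DNA replication had median log2 ratios of 0.40 at 30 h and 0.56 at 36 h, at the 99.8th and 99.9th percentile. These signs at 30 and 36 h held under all 5 scalings, while the sizes moved. With no scaling the median log2 ratios at 30 and 36 h were -0.46 and -0.77 for the merozoite list, -0.61 and -1.90 for the export machinery, -0.85 and -0.59 for the ring stage, and DNA replication stood at 1.54 at 36 h.

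The 7 transcripts for enzymes of phospholipid synthesis, the pathway that bisthiazolium compounds act on, had medians 1.57-, 1.58- and 1.65-fold lower at 24, 30 and 36 h. The median at 24 h lay at the 1.55th percentile of the random lists, and those at 30 and 36 h lay inside the random range, at the 19.3rd and 29.01st. The direction turned with no scaling, which gave median log2 ratios of 0.07 at 30 h and 0.28 at 36 h. At 36 h, 6 of the 9 transcripts for haemoglobin digestion, the supply of amino acids in the food vacuole, were at least 2-fold lower, with a median log2 ratio of -1.10. This lay inside the random range, at the 9.79th percentile, and was -0.10 with no scaling. The 12 proteasome transcripts had a median log2 ratio of -0.64 at 24 h, with 12 of 12 below 0, and medians of 0.23 at 30 h and 0.28 at 36 h. With no scaling the latter were 0.96 and 1.28. At 30 min the histone list had a median log2 ratio of 0.57 (99.9th percentile), the proteasome list 0.43 (97.7th) and the ribosomal RNA features 0.36 (98.1st). At 5 h the ring-stage list had a median of -0.43 and the ribosomal RNA features -0.51. These signs at 30 min and 5 h held under all 5 scalings, while some sizes did not. With quantile normalization the ring-stage median at 5 h was -0.04, at the 37.6th percentile, and the histone median at 30 min was 0.31.

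**Figure D2:**
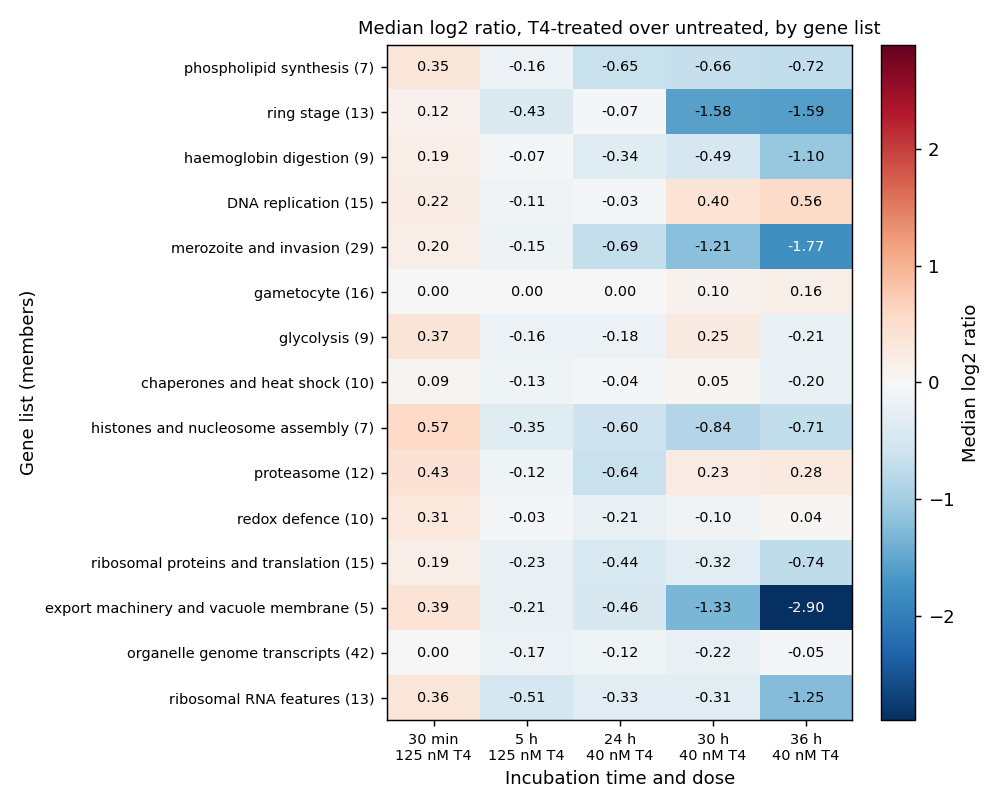
Median log2 ratio of the T4-treated over the untreated array (colour scale and cell values) for 15 gene lists (vertical axis, number of members in parentheses) at each incubation time and dose (horizontal axis). The lowest cells are those of the export machinery at 36 h, at -2.90, and of the merozoite and invasion list at 36 h, at -1.77, and the ring-stage list stood at -1.58 and -1.59 at 30 and 36 h.

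The T4 effect in the 40 nM experiment asked which transcripts changed over the 24, 30 and 36 h pairs together, each time standing as a repeat. The merozoite and invasion list fell, with a mean log2 change of -1.26 (adjusted p = 8.36e-09 by limma's camera with a preset correlation, adjusted p = 0.562 with an estimated correlation). By the same test 7 further lists fell, each with an adjusted p of at least 0.562 with an estimated correlation. These were phospholipid synthesis (mean log2 change -0.75), the ring stage (-1.16), haemoglobin digestion (-0.66), export machinery (-1.53), histones (-0.77), ribosomal proteins (-0.54) and organelle genome transcripts (-0.40). The organelle list no longer passed without features that share one value per array (adjusted p = 0.232). The DNA replication list rose by 0.24 on the log2 scale and the gametocyte list by 0.30 (adjusted p = 0.643 and 0.562 with an estimated correlation). The remaining 5 lists, with glycolysis, chaperones, the proteasome, redox defence and ribosomal RNA, did not pass the test.

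These list calls come from limma's camera with a preset correlation between genes and an adjustment over 15 lists. Beside that of the merozoite list, the adjusted p was 0.00184 for ribosomal proteins, 0.00753 for histones, 0.0133 for phospholipid synthesis and for export machinery, and 0.0167 for organelle transcripts. It was 0.0374 for haemoglobin digestion and for DNA replication, 0.0441 for gametocytes and 0.04996 for the ring stage. None of these calls held with an estimated correlation, where the adjusted p was 0.643 for DNA replication, 0.573 for organelle transcripts and 0.562 for the other 8 lists. The 5 lists that did not pass had adjusted p from 0.238 to 0.918 with the preset correlation. Among these, the chaperone, proteasome and redox lists ranked above other genes in the test although their mean log2 changes were -0.16, -0.02 and -0.08. Quantile normalization left 2 lists past the threshold, merozoite and invasion and DNA replication, and no scaling left 4. The merozoite, ring-stage, export and histone lists were those 4, and with quantile normalization the medians of the histone and ribosomal protein lists at 36 h were 0.33 and 0.09.

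Gene by gene, limma called no transcript over the 24, 30 and 36 h pairs among 4512 tested, with a smallest adjusted p of 0.0726, and 1335 stood at an unadjusted p under 0.05 (225.6 expected by chance). Of 2922 genes above the floor on all 6 arrays, 534 were higher and 858 lower at all 3 times, 47.6% in all. Independent times with even signs would give 25%. The 30 and 36 h ratios had r of 0.783 and so were not independent, and 25% is too low a bound for chance. The next counts were adjusted over each list alone and not over the 15 lists. By them 23 of 29 merozoite and invasion transcripts and 7 of 13 of the ring stage were lower. So were 4 of 7 of phospholipid synthesis, 5 of 9 of haemoglobin digestion, 6 of 7 of histones and 3 of 5 of export machinery. Lower too were 4 of 15 of ribosomal proteins, 12 of 33 of organelle transcripts and 1 of 10 of chaperones. By the same count 1 of 15 transcripts of DNA replication was higher and none of the 12 of gametocytes.

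The pairs at 30 and 36 h were much alike, and leaving out the 24 h pair, an alternative set out before the data were examined, changed the count of calls from 0 to 1520. That this fit is described in detail was decided after its result was seen. It covered the 4 remaining pairs of both experiments and had 2 residual degrees of freedom. Its SEs and adjusted p-values therefore measure how alike the 30 and 36 h pairs were, and the 30 min and 5 h pairs. They do not measure the spread between cultures of one time, so the calls do not show a replicated effect of T4. REX1 fell 15.3-fold (log2 change -3.93, SE 0.42, limma adjusted p = 0.000294), and EBA140 (MAL13P1.60), a ligand with which merozoites bind red cells, fell 12.2-fold (-3.60, SE 0.41, adjusted p = 0.000414). PTEX150 (PF14_0344), a core part of the protein export channel, fell 9.02-fold (-3.17, SE 0.32, adjusted p = 0.000216). MDV1 rose 4.59-fold (2.20, SE 0.34, adjusted p = 0.00158). ECT (PF13_0253), the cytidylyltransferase of phosphatidylethanolamine synthesis, fell 4.0-fold (-2.00, SE 0.29, adjusted p = 0.00122). Sizes from this fit are those with median scaling, and a call under all 5 scalings does not mean that the size held.

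In that fit 25 of 29 merozoite and invasion transcripts fell (12 with no scaling), 11 of them under all 5 scalings. Examples are AMA1 (PF11_0344), an adhesin of the moving junction, which fell 3.51-fold (SE of log2 0.32), its partner RON2 (PF14_0495), which fell 4.02-fold (SE 0.26), and SUB1 (PFE0370c), a protease needed for egress, with a log2 change of -2.48 (SE 0.32). The kinase CDPK1 (PFB0815w) had a log2 change of -2.02 (SE 0.29). RH5, the ligand of basigin, was at the floor in the treated culture at 36 h, at least 5.12-fold below the untreated. The egress-associated proteins SERA5 and SERA6, with log2 changes of -0.45 and 0.43, did not pass. Of the ring-stage list 7 of 13 fell, 6 of them under all 5 scalings, while KAHRP and PfEMP3 of this list were at the floor on all 6 arrays and could show no change. These 6 were the vacuole membrane proteins ETRAMP2 (log2 change -3.09) and ETRAMP10-1 (-3.47), and SBP1 (-3.32), REX1, REX2 (-3.37) and REX3 (-3.54), which belong to Maurer's clefts or are exported to the red cell. ETRAMP10-2 of the same list rose past the threshold in 4 of 5 scalings, though not with median scaling.

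Of the 5 export transcripts 4 fell, and PTEX150, PTEX88 (log2 change -2.83) and TRX2 (-2.11) did so under all 5 scalings. HSP101 (PF11_0175), the chaperone that unfolds cargo for the same channel and a member of the chaperone list, fell 8.97-fold (SE of log2 0.38, adjusted p = 0.000560). In phospholipid synthesis 3 of 7 fell. ECT did so under all 5 scalings, ethanolamine kinase (EK, PF11_0257) fell 2.46-fold and in 4 of 5, and phosphatidylserine decarboxylase (PSD, PFI1370c) had a log2 change of -0.92 and passed in 2 of 5. The enzymes nearest to choline, choline kinase (CK, log2 change -0.78, adjusted p = 0.0588) and phosphoethanolamine methyltransferase (PMT, -0.36, adjusted p = 0.336), did not pass. In haemoglobin digestion 4 of 9 fell, and plasmepsin I (PMI, PF14_0076), which fell 4.35-fold, did so under all 5 scalings. With no scaling 1 of the 9 fell and 2 rose, and PMIII of this list rose past the threshold in 4 of 5 scalings.

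Transcripts that rose at 30 and 36 h included 4 of 15 of DNA replication, and 7 with cyclic loess, 9 with quantile normalization or a common 90th percentile and 12 with no scaling. The origin recognition proteins ORC1 (PFL0150w) and ORC5 (PFB0720c) rose 2.38- and 3.28-fold and the helicase subunit MCM2 (PF14_0177) 1.93-fold, each under all 5 scalings, whereas topoisomerase II (TOP2) fell with a log2 change of -1.38 in 4 of 5. ORC5 was at the floor in the untreated culture at 36 h. Of 12 gametocyte transcripts 2 rose, MDV1 under all 5 scalings and the surface protein Pfs47 in 4 of 5. GRP94 (PFL1070c), a chaperone of the endoplasmic reticulum, rose 2.45-fold and thioredoxin reductase (TrxR, PFI1170c) 1.79-fold, while the variant histone H2A-Z (PFC0920w) fell 3.13-fold, each under all 5 scalings. The calls for several other lists turned with the scaling. With median scaling none of 12 proteasome and none of 9 glycolytic transcripts rose and 1 of 10 for chaperones did, whereas under the other scalings 4 to 10 proteasome, 4 to 7 glycolytic and 4 to 7 chaperone transcripts rose. Of 7 histone and 15 ribosomal protein transcripts 3 and 4 fell with median scaling, and among these H2A-Z alone fell under all 5. Of 33 organelle transcripts 15 fell and 1 rose, and of 13 ribosomal RNA features 4 fell, but none of these falls held under all 5 scalings. Features that share one value per array made up 10 of the 15 and 3 of the 4, so those falls are no evidence of separate transcripts.

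**Figure D3:**
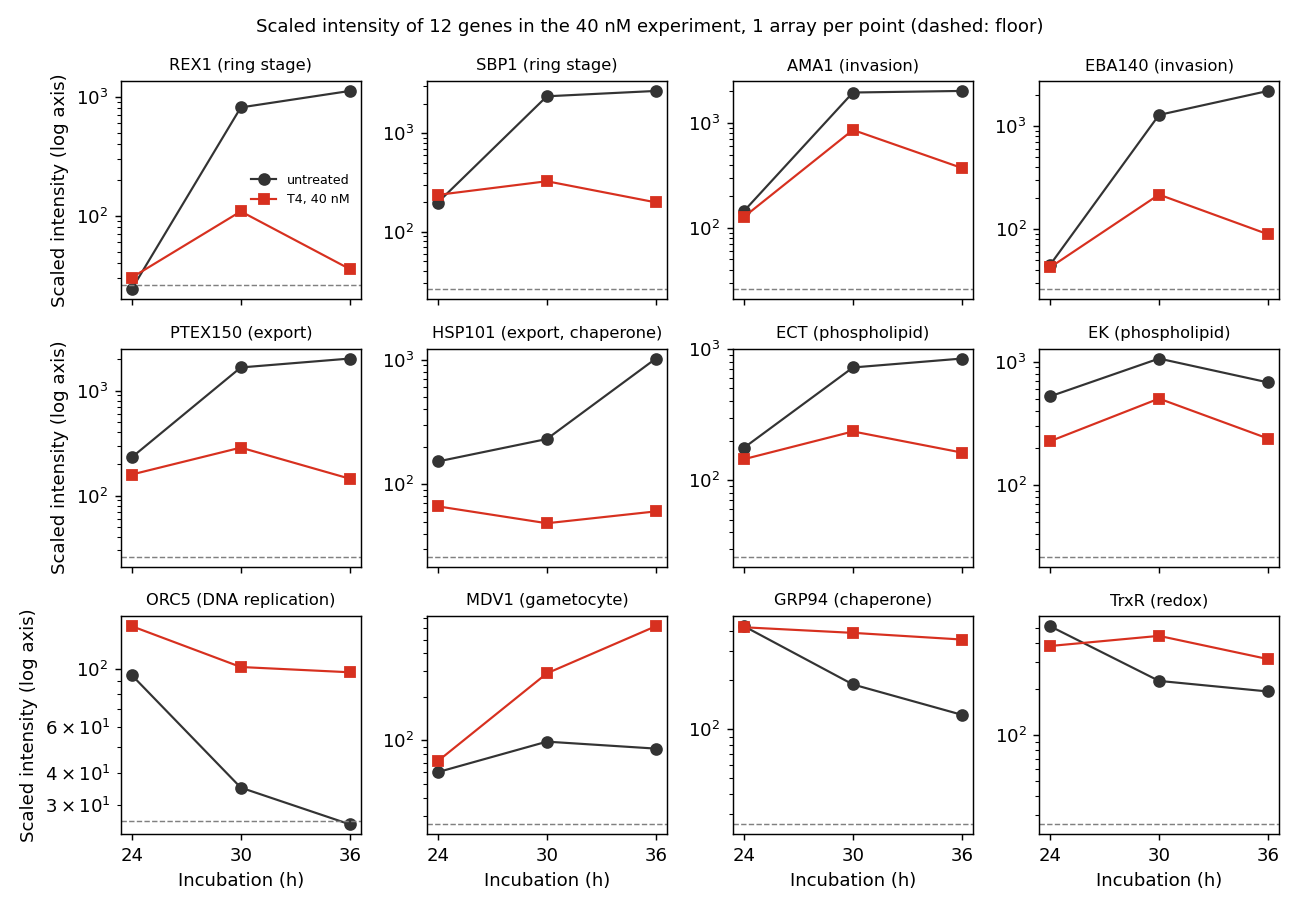
Scaled intensity (log axis) of 12 genes in the 40 nM experiment against incubation time (h), with 1 array per point, for untreated and T4-treated cultures, and the intensity floor of 26.1 as a dashed line. With scaling to a common median, REX1 was 31.3-fold lower and EBA140 24.8-fold lower in the treated culture at 36 h, and MDV1 was 7.07-fold higher.

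In all, 542 transcripts rose and 978 fell at 30 and 36 h. The split moved with the scaling, to 632 and 546 with quantile normalization, 1221 and 244 with no scaling, 1059 and 457 with a common 90th percentile and 600 and 721 with cyclic loess, and 390 rose and 242 fell under all 5. Of the 542 that rose 340 had a positive log2 ratio at 24 h, and of the 978 that fell 522 had a negative one.

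The T4 effect in the 125 nM experiment asked what changed within the first hours of exposure. No list and no gene passed the test there. Thioredoxin 1 (Trx1, PF14_0545), a redox protein, was the one member of the gene lists among the 24 genes that the rule picked. It had log2 ratios of 0.51 at 30 min and 0.71 at 5 h. The organelle list had the smallest adjusted p, at 0.0677, followed by the proteasome list at 0.111, and with an estimated correlation every list lay between 0.966 and 0.987. Without features that share one value per array, the organelle list had an adjusted p of 0.551 by camera. By limma 0 of 4512 genes passed and 38 stood at an unadjusted p under 0.05, fewer than the 225.6 expected by chance. The residual spread is shared with the 40 nM experiment, so this test is strict for small changes at 125 nM. Among 3497 genes above the floor on all 4 arrays, 903 were higher and 740 lower at both times, against 50% of genes by chance.

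Over all 5 times and both doses, the question was which genes moved one way throughout. Limma called 0 genes, with 546 at an unadjusted p under 0.05 and a smallest adjusted p of 0.386. The comparison of the experiments asked where the T4 effect at 40 nM differed from that at 125 nM, with dose and incubation time changing together. The merozoite and invasion list differed by a mean log2 of -1.28 and the export machinery by -1.62, while the gametocyte list differed by 0.40. Camera called 1 list with a higher and 6 with a lower effect at 40 nM, and none with an estimated correlation (adjusted p from 0.599 to 0.805). By gene limma called 0, with 432 at an unadjusted p under 0.05, and without the 24 h pair it called 544.

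The untreated cultures show how transcripts changed with time in the absence of the drug. Between 24 and 30 h the merozoite and invasion transcripts had a median 9.30-fold higher, with 24 of 29 at least 2-fold higher, and at 36 h the median was 9.20-fold above that at 24 h. Between 24 and 30 h the glycolytic transcripts had a median log2 ratio of -1.19 and the proteasome transcripts one of -1.03. Of the 15 transcripts of DNA replication 11 were at least 2-fold lower at 36 than at 24 h. The signs of these list medians held under all 5 scalings. The ring-stage list had a median 1.58-fold higher at 30 than at 24 h, with 6 of 13 members at least 2-fold higher. With no scaling that median log2 ratio was 0. In all, 860 genes were at least 2-fold higher and 732 lower at 30 than at 24 h, 718 and 844 at 36 than at 24 h, and 214 and 340 at 36 than at 30 h. In the other experiment 166 were higher and 128 lower at 5 h than at 30 min.

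The similarity of the T4 change between times was described by correlations across 4512 genes, which are not independent replicates. The log2 ratios at 30 and 36 h had a Pearson r of 0.783 and a Spearman rho of 0.744. Of the genes 2-fold apart at both times, 204 were higher and 448 lower at each, against 44.6 and 135.7 if the lists were independent among the 4020 genes that could be counted at both times. The 24 h ratios had r of 0.189 with those at 30 h and 0.163 with those at 36 h, and the 30 min and 5 h ratios had r of -0.053.

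The T4 change against untreated development asked whether the treated culture differed from its partner along the course of the parasite cycle. EBA140, AMA1 and other merozoite transcripts lower with T4 at 36 h belonged to those that untreated cultures made more of from 24 to 30 h. Of the 957 genes at least 2-fold lower with T4 at 36 h, 533 (55.7%) were at least 2-fold higher at 30 than at 24 h without drug, against 16.7% of all genes. Of the 582 higher with T4 at 36 h, 186 (32.0%) were lower there, against 14.2% of all genes. Across 4512 genes the log2 ratio at 36 h and the untreated change from 24 to 30 h, which share no array, had r of -0.561 and rho of -0.452. The ratio at 24 h and the untreated change from 30 to 36 h had r of 0.000336. The treated 36 h array had a rho of 0.845 with the untreated 24 h array, 0.80 with the untreated 30 h array and 0.769 with the untreated 36 h array, and its highest, 0.922, with the treated 30 h array.

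**Figure D4:**
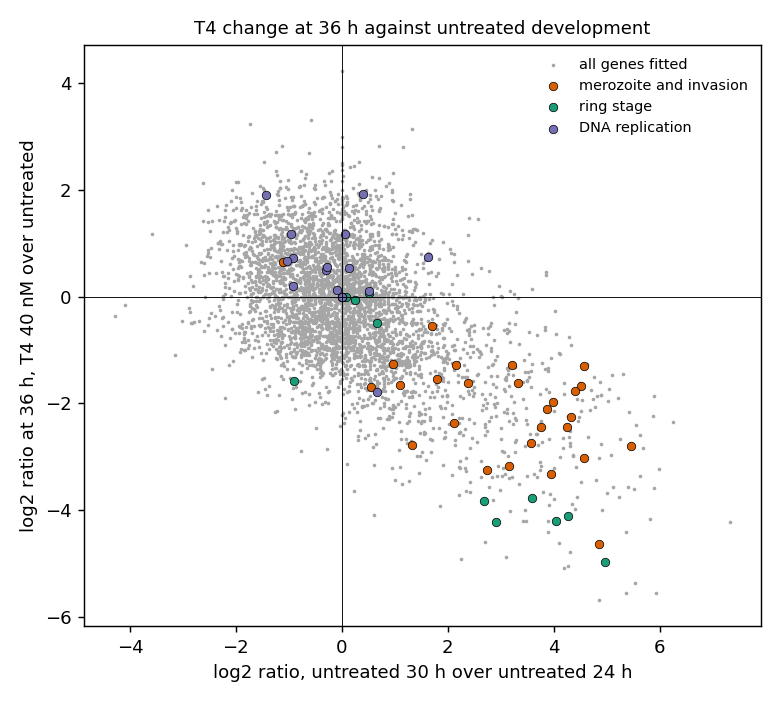
Log2 ratio of T4-treated over untreated at 36 h (vertical axis) against the log2 ratio of untreated 30 h over untreated 24 h (horizontal axis), with 1 point per gene and the members of selected lists in colour. Across 4512 genes r was -0.561, and merozoite and invasion transcripts lie at the lower right, higher at 30 h without drug and lower with T4 at 36 h.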

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

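The tests of a 24 h sample labelled 36 h and of slower progress at 36 h were chosen only after the result was seen, as was the alternative without features at a shared value, and the test of lost stretches was set out after some of the silent genes had been noticed. The readings of that test, of the mixture test and of the test matched on untreated development were widened after their values were known. Lists differed between the experiments by the test of the difference itself (40 nM minus 125 nM, mean log2), at -0.75 for phospholipid synthesis, -0.79 for haemoglobin digestion, -1.28 for merozoite and invasion, 0.40 for gametocytes, -0.88 for histones, -0.57 for ribosomal proteins and -1.62 for export machinery. Dose and incubation time change together between the experiments, and no list passed with an estimated correlation (adjusted p from 0.599 to 0.805).

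The treated 36 h array was nearer to the untreated 24 h array (rho 0.845) than to its own untreated partner (0.769). Signal near background was argued against, since among 1204 genes at least 4 times the floor on all 6 arrays the difference of rho was 0.081. A 24 h sample labelled 36 h was argued against as well, since the array's rho with the treated 30 h array exceeded that with either 24 h array by 0.0708. For a mixture of the untreated 24 h and 36 h states, 173 genes lay at least 2-fold above and 245 at least 2-fold below both, 12.7 times as many as the 33 genes 2-fold apart in the 5 h pair. The 5 h pair was the quietest, which made the bound set beforehand wrong. Over 5 scalings the genes outside both were 1.26 to 2.36 times as many as those 2-fold apart in the 24 h pair. Against the 30 min pair they were 3.32 times as many with median scaling and 1.56 to 2.70 times with the other scalings. A mixture therefore stays open. Slower progress through the cycle under T4 may account for part of the change (r of -0.561 between the T4 change at 36 h and untreated development). On a scale with untreated 24 h at 0 and untreated 30 h at 1, treated 36 h (0.38) stood behind treated 30 h (0.63). Untreated 36 h stood at 0.87, but untreated 30 h is fixed at 1 by the scale, so their order is no gauge for the treated arrays. Treated 36 h also had a higher rho with untreated 24 h (0.845) than treated 30 h had (0.779). With 1 array per condition, the order of the treated arrays decides nothing. At 36 h the export list lay below every random list matched on the untreated change from 24 to 30 h. That matching leaves out the untreated change from 30 to 36 h, in which the 5 export transcripts had a median log2 ratio of 0.28. The rank therefore does not exclude slower progress. Different starting stages of the cultures stay open and were not tested.

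The phospholipid synthesis list was lower in the 40 nM experiment, and T4 is a choline analogue aimed at that pathway. The mean log2 ratio of its members over 24, 30 and 36 h had a median at the 9.61th percentile of random lists matched on mean expression, so a lower signal of bright genes on the treated arrays may account for that mean. At 24 h alone the list lay at the 1.55th percentile of such lists, below the random range. The random lists take genes as independent, and even at 5 h 3 of 15 lists lay outside that range. The value at 24 h therefore does not exclude that signal. Matched on untreated development instead, the mean over the 3 times stood at the 3.04th percentile. That matching uses untreated arrays that are part of the ratios ranked, so this value decides nothing. Matched on an untreated change that shares no array with the ratio, the list stood at the 0.29th percentile at 24 h, the 5.49th at 30 h and the 18.2th at 36 h. Slower progress may account for the values at 30 and 36 h. At 24 h it stays open, since the untreated change from 30 to 36 h is a poor measure of progress there. A response of this pathway to the drug stays open, since no test here separates it from these.

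A set of 9 genes, KAHRP, PfEMP3 and RH2B among them, was at least 4 times the floor on all 4 arrays of the 125 nM experiment and at the floor on all 6 arrays of the 40 nM experiment, and no gene showed the opposite. KAHRP, the main protein of the knobs on infected red cells, had scaled intensities from 4052 to 5466 in the first and from 8.7 to 25.1 in the second. Loss of chromosome stretches in the cultures of the 40 nM experiment was tested by neighbourhood, and no uninterrupted stretch of genes at the floor held more than 2 of the 9 (PfEMP3 beside KAHRP, and a second pair on another chromosome), which 200 of 10000 shuffled orders gave as well, none more. Another gene of the set lies on the chromosome of PfEMP3 and KAHRP, parted from them by 2 measured genes whose highest scaled intensity in the 40 nM experiment was 35.1, little above the floor of 26.1. The bound set beforehand, at most 2 genes in a stretch to count against losses, was wrong, since a stretch of 2 lies above all but those 200 shuffled orders and genes so near the floor can break a stretch. Such losses stay open, and a stage difference between the experiments was not tested.

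The organelle transcript list had an adjusted p of 0.232 without features at one shared value per array, against 0.0167 with them.

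Of the 10 splits of the 6 arrays of the 40 nM experiment into 3 and 3, the real one gave 1335 genes at an unadjusted p under 0.05 and the highest other 1089. With 1 of 10, the real one itself, the splits are too few for a share under 0.05, and among the 4 splits that part every pair the highest other was 732. Over all 5 times, 16 of 100 drawn splits, the real one included, gave at least its 546 genes, and the highest other gave 1561. That split parted 3 pairs, and a parted pair still compares a treated with an untreated array. The 16 therefore do not measure chance alone. Of the 14 drawn splits that part all 5 pairs, 2 gave as many, the real one included, so chance cannot be excluded there. The highest other among these gave 684, while the other drawn splits put both arrays of some pair in one group.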

How the results depend on the processing

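Scaling to a common 90th percentile, cyclic loess, features at a shared value, the list tests of the difference between experiments and the combinations of the 24 h pair with each scaling were chosen after seeing the data. The list medians of phospholipid synthesis at 30 and 36 h turned to 0.07 and 0.28 with no scaling, and those of histones and ribosomal proteins at 36 h to 0.33 and 0.09 with quantile normalization. The majority of genes 2-fold apart at 36 h turned from lower to higher with no scaling (1606 and 295). Calls of single lists were lost in 61 combinations of list and setting and gained in 3 at 40 nM, gained in 4 at 125 nM, and lost in 39 and gained in 9 for the difference. Low signal over background limits what can be seen of dim genes. Genes 2-fold apart numbered 33 at 5 h, 894 at 30 h and 1539 at 36 h. No scaling gave 377 at 30 min and 69 at 5 h, the 10th-percentile floor 276 and 98, the 40th-percentile floor 66, 14 and 150 (24 h), and the 90th percentile 214 at 30 min. A 3-fold threshold gave 16, 5, 36, 296 and 618, as its construction implies.

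The 40 nM effect had 0 genes past the threshold in limma (1335 at an unadjusted p under 0.05), 41 with the 10th-percentile floor, and from 0 to 1520 with pairs left out in turn. The 1520 came without the 24 h pair, which became 1465 with no scaling, 1178 with quantile normalization, 1516 with the 90th percentile and 1321 with loess. Without the 30 h or 36 h pair it was 0 (497 and 583 unadjusted). Without the pair block 577 genes stood at an unadjusted p under 0.05. The difference between experiments ranged from 0 to 544 genes, the latter without the 24 h pair. The 125 nM effect and that over all times stayed at 0 in limma.

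Lists past the threshold at 40 nM numbered 10, but 4 with no scaling, 2 with quantile normalization, 5 with the 40th-percentile floor, 6 with loess, 0 with an estimated correlation, 0 with fry, and from 5 (without 36 h) to 9 with pairs left out. At 125 nM the count of 0 became 1, the organelle list, with no scaling, the 40th-percentile floor, the 90th percentile and loess. With median scaling and without features at a shared value, that list had an adjusted p of 0.551 by camera. For the difference, 7 became 1 with quantile normalization, 1 with loess, 0 with an estimated correlation, 0 with fry, and from 1 (without 30 min) to 9 with pairs left out. Lists outside the random range at 24 h went from 4 to 2 with quantile normalization. The correlation with untreated development was -0.452 by Spearman. Untreated genes apart between 30 min and 5 h went from 294 to 505 with no scaling, 465 and 194 with the lower and higher floor, and from 30 to 36 h from 554 to 846 with the 10th-percentile floor. Apart from the fewer genes and samples that some of these settings use, the cause was not tested.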

Other observations

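The untreated cultures of the 125 nM experiment also differed between 30 min and 5 h. The merozoite and invasion list had a median log2 ratio of 0.60 and the histone list 0.67, while the ribosomal RNA features had -0.47, with the same signs under all 5 scalings.

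The arrays of the 40 nM experiment were also placed along untreated development by all 4512 genes tested. On a scale with untreated 24 h at 0 and untreated 30 h at 1, treated 24 h stood at 0.04, treated 30 h at 0.63, untreated 36 h at 0.87 and treated 36 h at 0.38. The T4 change at 36 h was also ranked in random lists matched on the untreated change from 24 to 30 h, which shares no array with it. The merozoite and invasion list stood at the 20.8th percentile, the ring-stage list at the 3.6th, DNA replication at the 98.9th, haemoglobin digestion at the 0.08th and ribosomal proteins at the 0.07th. The export list lay below every matched random list. These random lists were not matched on expression. With lists matched on mean expression, haemoglobin digestion at 36 h stood at the 9.79th percentile and ribosomal proteins at the 63.5th, both inside the random range.

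Treated and untreated arrays were close at the earlier times, with a rho of 0.946 between the treated and untreated arrays at 30 min, 0.974 at 5 h and 0.946 at 24 h. A set of 50 features carried nearly one value on at least 4 arrays, 28 of them on all 10, and 14 of the 42 organelle features and 4 of the 13 ribosomal RNA features were among them.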
